A study of Homo sapiens with 9 samples.

How the data were processed

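RNA from H441 cells, an established human lung adenocarcinoma line with features of distal airway and alveolar epithelium, was measured on 9 Affymetrix Human Genome U133 Plus 2.0 arrays, 3 per group. Per the labels, 3 arrays carried RNA of cells with a short hairpin RNA against KLF5 (knockdown), 3 of cells with added KLF5 (overexpression) and 3 of control cells. KLF5 is a zinc-finger transcription factor of epithelial cells. The labels name the control in different ways: a nontargeting hairpin on the samples and an empty retroviral vector in the series' design text. Which is right was not settled here. The arrays labelled overexpression did not have higher KLF5 signal than control, so groups are called by their labels throughout.

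The authors deposited 1 table of log2 values, 1 column per array, with 54675 probe sets. Per the submitters' processing notes the values came from RMA, which corrects the background of each array, quantile normalises the probes over arrays and summarises each probe set by median polish. The software, its version and the probe set definition are not given in the sources used here. The deposited log2 values ran from 2.93 to 15.6, and every column belonged to a labelled sample. RMA values are relative brightness on a log2 scale, so levels of different probe sets are not comparable, and folds of dim probe sets are compressed. Arrays have no read depth. Their number limits the precision: 3 against 3 cannot give an exact permutation p below 0.1 for a single value.

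The 62 Affymetrix control probe sets were left out, and the other 54613 were tested. Gene names came from the platform annotation, updated through its gene identifiers: 41091 probe sets had 1 gene, 1801 had several and 11721 had none listed. The 41091 probe sets covered 19775 genes. For each gene the probe set with the highest mean over the 9 arrays was used, taking a probe set with the ending _x_at only where the gene had no other. Endings _x_at and _s_at mark probe sets that can detect more than 1 transcript.

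Tests used limma 3.58.1 in R 4.3.3. A linear model with 3 group means was fitted to all 9 arrays (6 residual degrees of freedom), with lmFit and eBayes, and 3 contrasts were tested: knockdown minus control, overexpression minus control, and overexpression minus knockdown. Adjusted p is the Benjamini-Hochberg value over all 54613 probe sets within a contrast, and a probe set below 0.05 is said to have risen or fallen. Alternatives that test fewer probe sets, or genes, adjust over those tested. A moderated F test asked for any difference among the 3 groups. SE is the moderated standard error, and n is 3 arrays per group throughout. Calls in both contrasts against control share the 3 control arrays, so unchanged groups with a shared control were simulated in 20 draws. All 9 arrays, control included, were drawn around each probe set's mean with its SD pooled within the 3 groups. The overlap of independent lists was computed from the number of calls in each contrast.

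The 27 gene lists were fixed before the data were examined, as were the groups, the tests and the alternatives. They were: alveolar type II cell and surfactant; airway secretory cell and mucin; squamous and basal epithelial; epithelial junction and polarity; mesenchymal transition; mitosis; DNA replication; p53 targets and cell cycle inhibitors; cholesterol synthesis and uptake; fatty acid and lipid synthesis; hypoxia and glycolysis; interferon response; unfolded protein and amino acid stress; ERK pathway response; TGF-beta response; NF-kB and inflammatory mediator; Wnt and intestinal-type epithelial; KLF family; KLF5 targets reported in other cells; apoptosis regulators; NRF2 and xenobiotic response; integrin and matrix adhesion; ion channel and transporter of lung epithelium. Markers of other cell types made the remaining 4: fibroblast, endothelial, leukocyte, and retrovirus packaging cell (kidney and neural). Of the 627 list members, 579 were measured. Each list was tested with camera (preset correlation 0.01) on 1 probe set per gene, with Benjamini-Hochberg over the 27 lists, then again with the correlation estimated per list, and with fry. Members of a list were also adjusted over the list alone. Lists such as the KLF5 targets and the apoptosis regulators were not split by direction of regulation, so camera can miss members that move opposite ways.

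Named genes followed a rule fixed before the data were examined. It took KLF5; the 10 genes with the largest rise and the 10 with the largest fall against control in each group, among genes below the threshold whose groups of 3 did not overlap, without uncharacterised loci; the 10 genes called in opposite directions with the largest smaller change; and up to 4 members per list with the smallest adjusted p. Of these, the text gives the ones that matter.

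The scripts were tested on simulated data with each probe set's own mean and within-group SD, with 200 of 54613 probe sets changed. In knockdown minus control, 43.3% of changes of 0.5 on the log2 scale, 88.1% of changes of 1 and 100% of changes of 2 were recovered, with 13 false calls. In overexpression minus control the shares were 37.3%, 91% and 98.5%, with 6 false calls, and in overexpression minus knockdown 34.3%, 88.1% and 100%, with 1 false call.

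Alternatives were: the replicate number as a block; only the brighter probe sets; quantile normalisation again; cyclic loess; an intensity trend with a robust prior; array weights; no _x_at and _s_at probe sets; each array left out in turn; only the arrays of the groups compared; an absolute log2 fold change of at least 1; an adjusted p below 0.01; a test per gene; the mean of all probe sets of a gene; an estimated correlation or fry for the lists; and the other KLF5 probe set. The mean of both KLF5 probe sets was added after seeing the data. RNA quality was read from the Affymetrix control probe sets and from relative log expression, the difference of each probe set from its median over arrays. No present or absent calls and no scan dates were used here.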

Results

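Gene expression was measured in H441 lung adenocarcinoma cells on 9 arrays: 3 labelled KLF5 knockdown, 3 labelled KLF5 overexpression and 3 control arrays. By its labels, the series set a lower and a higher level of KLF5 against a common control. Values are RMA log2 intensities, and fold changes are differences of group means on the log2 scale, each with its standard error (SE) and n = 3 arrays per group. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Array medians ran from 6.87 to 6.99 over the arrays.

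KLF5 itself was read by 2 probe sets. The brighter, with the ending _s_at, had a mean of 10.77 ± 0.175 (SD, n = 3) in control, with 10.81, 10.58 and 10.92 in replicates 1 to 3. In the arrays labelled knockdown it read 10.45, 10.07 and 10.67 (10.40 ± 0.304), and in those labelled overexpression 10.32, 11.09 and 10.32 (10.58 ± 0.443). It differed from control by -0.38 (SE 0.214, adjusted p = 0.376) in the arrays labelled knockdown and by -0.19 (SE 0.214, adjusted p = 0.616) in those labelled overexpression. Neither was beyond the spread between replicates, to which replicate 2 labelled overexpression, the only one of its group above control, added. Without that array the differences were -0.38 (adjusted p = 0.0784) and -0.45 (adjusted p = 0.0913). With array weights they were -0.36 (adjusted p = 0.085) and -0.44 (adjusted p = 0.0506). The dimmer read 9.10, 9.50 and 9.09 in control, 8.61, 8.63 and 8.66 in the arrays labelled knockdown, and 8.60, 7.59 and 8.44 in those labelled overexpression. Its difference from control was -0.60 (SE 0.224, adjusted p = 0.137) in the arrays labelled knockdown, with no overlap between the groups. In the arrays labelled overexpression it fell by 1.02 (SE 0.224, adjusted p = 0.0269), a size to which the low replicate 2 (7.59) added. Values without that array and with array weights were read for the brighter probe set only. The mean of both probe sets, an alternative chosen after seeing the data and adjusted over genes, differed from control by -0.49 (adjusted p = 0.00208) and -0.61 (adjusted p = 0.00146). Replicate 2 labelled overexpression was the lowest array on the dimmer probe set and the highest on the brighter. These deviations cancel in the mean, so its small p-values rest partly on averaging 2 probe sets that disagree on that array. Neither probe set alone passed the threshold for a lower level in the arrays labelled knockdown, and neither had a mean above control in those labelled overexpression. Every direction below is therefore that of the label, not of the KLF5 level. Where these probe sets lie relative to the introduced KLF5 sequence was not analysed here, and a probe set outside that sequence would not report it.

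**Figure D1:**
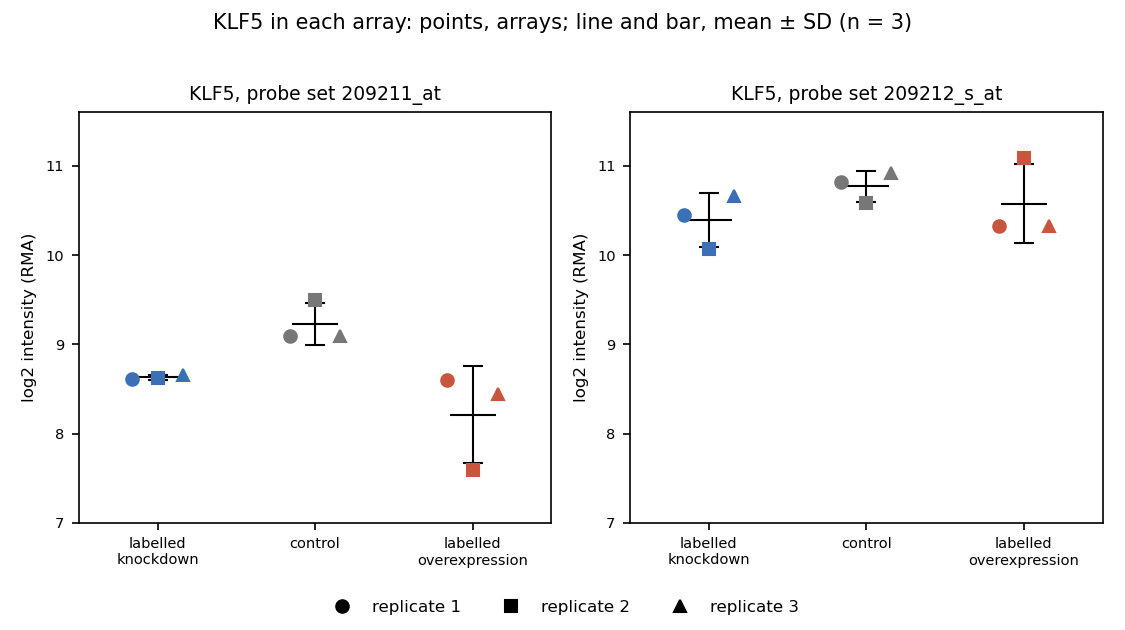
KLF5 log2 intensity in each array for the 2 KLF5 probe sets, with mean and SD of the 3 arrays per group. The dimmer probe set lay between 7.59 and 8.66 in both labelled groups, below all 3 control arrays, and replicate 2 labelled overexpression was lowest for the dimmer probe set and highest for the brighter.

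Replicate 2 labelled overexpression stood apart from every other array. Its correlation with the other arrays across probe sets was 0.985 to 0.990, against 0.998 to 0.999 for the other pairs within a group, and the interquartile range of its relative log expression was 0.37, against 0.0991 to 0.18 elsewhere. The gap between the KLF5 probe sets was 3.5 on this array and 1.08 to 2.01 on the others. On the first principal component, which held 40.5% of the variance, it lay at 76.7 and the other 8 arrays between -16.6 and 5.93. The second component, with 31.0%, separated control (-35.3 to -25.4) from the arrays labelled knockdown (28.0 to 32.2), with those labelled overexpression between (-3.42 to 3.15).

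**Figure D2:**
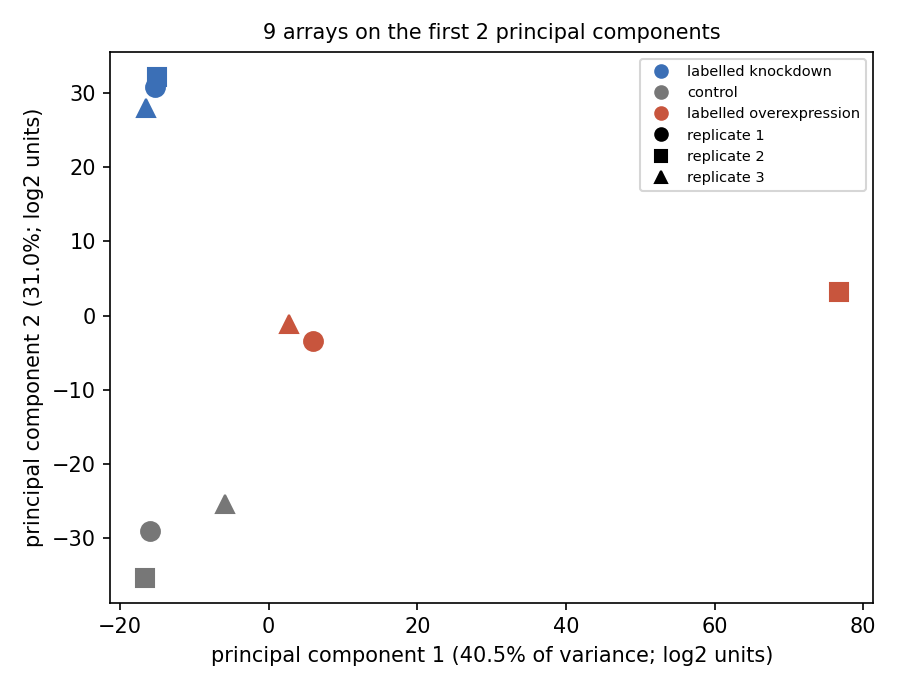
The 9 arrays on the first 2 principal components of all probe sets, in log2 units, coloured by labelled group with 1 marker shape per replicate number. Replicate 2 labelled overexpression lies at 76.7 on component 1, and the other 8 arrays between -16.6 and 5.93.

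Arrays labelled knockdown against control asked which genes differ after the hairpin against KLF5. Among the largest rises were AQP4 (2.99, SE 0.176, adjusted p = 1.97e-05) and AQP3 (2.77, SE 0.169, adjusted p = 2.07e-05), both water channels of epithelia. ABCG2, a drug efflux transporter (2.30, SE 0.172), DKK1, a secreted Wnt antagonist (2.26, SE 0.218), and the calcium-binding protein S100A4 (2.15, SE 0.0995) rose as well. TMT1A, a thiol methyltransferase, rose by 2.94 (SE 0.197) on a probe set with the ending _s_at. Without such probe sets its value was -0.03 (adjusted p = 0.94). The largest falls were in ARG2, the mitochondrial arginase (-3.65, SE 0.144, adjusted p = 3.29e-06), INHBE, an activin subunit (-3.52, SE 0.161, adjusted p = 5.52e-06) and TCIM (-3.33, SE 0.127). The zinc-binding secreted protein AZGP1 (-2.13, SE 0.127) and UPP1, a uridine phosphorylase (-1.94, SE 0.0845), fell too. Further rises were in KRT4 (1.76), TMT1B (1.75), TM4SF18 (1.72) and UGT8 (1.72). Further falls were in the vitamin B12 binder TCN1 (-1.87), NIBAN1 (-1.82), PLAC1 (-1.77), the clock factor NPAS2 (-1.76) and TCP11L2 (-1.76).

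Cholesterol genes rose together in the arrays labelled knockdown. Of 18 measured members of cholesterol synthesis and uptake, 11 rose, none fell and 7 were not called, also when adjusted over the list alone (camera adjusted p = 1.09e-09, and adjusted p = 0.0312 with an estimated correlation). They included INSIG1 (1.62, SE 0.0991), the sterol sensor partner, LSS (1.02, SE 0.0711), STARD4 (1.23, SE 0.0885) and DHCR7 (0.88, SE 0.0647). Unfolded protein and amino acid stress genes went the other way: of 26 measured, 14 fell, 2 rose and 10 were not called (14 and 3 adjusted over the list alone; camera adjusted p = 4.09e-05, and adjusted p = 0.0312 with an estimated correlation). ATF3 (-1.32, SE 0.0857), TRIB3 (-1.13, SE 0.0746), CHAC1 (-1.09, SE 0.0947) and CEBPB (-0.83, SE 0.077), all induced in the amino acid stress response, were among those that fell. These 2 lists were the only ones whose calls held with an estimated correlation in this comparison.

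DNA replication had 20 of 29 measured members higher, none lower and 9 not called (23 higher adjusted over the list alone; camera adjusted p = 5.36e-13, but adjusted p = 0.151 with an estimated correlation). DNA ligase LIG1 rose by 1.16 (SE 0.0986), thymidylate synthase TYMS by 1.04 (SE 0.0934) and the polymerase subunit POLE2 by 0.89 (SE 0.0836). In mitosis, 4 of 30 rose, none fell and 26 were not called (5 higher adjusted over the list alone; camera adjusted p = 0.0238, but adjusted p = 0.455 with an estimated correlation and 0.0505 without control replicate 3). KIF20A was at 0.70 (SE 0.0929) and MAD2L1 at 0.51 (SE 0.0735). Among p53 targets and cell cycle inhibitors, 6 of 20 fell, 2 rose and 12 were not called (8 and 2 adjusted over the list alone; camera adjusted p = 0.0321, but adjusted p = 0.383 with an estimated correlation, 0.062 without dim probe sets, 0.0565 without knockdown replicate 2, and 0.0556 after cyclic loess). SESN2 (-1.61, SE 0.101), GADD45A (-0.64, SE 0.0722) and MDM2 (-0.86, SE 0.138) were among those lower. SESN2 and GADD45A are also induced by amino acid stress.

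Interferon response had 14 of 30 measured members lower, 4 higher and 12 not called (15 and 4 adjusted over the list alone; camera adjusted p = 3.75e-05, but adjusted p = 0.197 with an estimated correlation). The antiviral gene IFIT3 was at -1.13 (SE 0.0768), OASL at -1.17 (SE 0.0947) and IFIT1 at -1.18 (SE 0.125). In hypoxia and glycolysis, 10 of 27 rose, 2 fell and 15 were not called (13 and 4 adjusted over the list alone; camera adjusted p = 0.0173, but adjusted p = 0.455 with an estimated correlation). The glycolytic enzymes ENO2 (1.35, SE 0.127) and ALDOC (1.22, SE 0.14) rose, while VEGFA (-0.85, SE 0.112), the angiogenic factor, and DDIT4 (-0.68, SE 0.0718) fell. In the ion channel and transporter list, 8 of 19 rose, 1 fell and 10 were not called (10 and 1 adjusted over the list alone; camera adjusted p = 0.000338, but adjusted p = 0.151 with an estimated correlation), among them AQP4 and AQP3 above and the chloride transporter SLC26A9 (0.80, SE 0.119). Integrin and matrix adhesion had 9 of 27 higher, none lower and 18 not called (9 and 1 adjusted over the list alone; camera adjusted p = 0.00748, but adjusted p = 0.175 with an estimated correlation), including the metalloproteinase inhibitors TIMP1 (0.88, SE 0.07) and TIMP2 (1.59, SE 0.181) and the metalloproteinase MMP7 (0.73, SE 0.0956).

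Of 16 alveolar type II and surfactant members, 6 rose, 2 fell and 8 were not called (7 and 2 adjusted over the list alone; camera adjusted p = 0.0348). The surfactant lipid enzyme LPCAT1 was at 0.99 (SE 0.094) and the protease NAPSA at 0.54 (SE 0.0697). The alveolar call was lost with an estimated correlation (adjusted p = 0.187 with an estimated correlation), without knockdown replicate 2 (0.0565), without control replicate 1 (0.0515) and without _x_at and _s_at probe sets (0.24). In the KLF family, 4 of 19 fell, 1 rose and 14 were not called (5 and 1 adjusted over the list alone; camera adjusted p = 0.0372). KLF11 was at -0.86 (SE 0.0963) and KLF3 at -0.56 (SE 0.0854). The family's call was lost with an estimated correlation (adjusted p = 0.384 with an estimated correlation), without knockdown replicate 2 (0.0565), without control replicate 2 (0.0601), without dim probe sets (0.0684) and without _x_at and _s_at probe sets (0.207). Mesenchymal transition had 5 of 20 higher, 1 lower and 14 not called (6 and 1 adjusted over the list alone; camera adjusted p = 0.0436), led by S100A4 and the matrix protein TGFBI (0.63, SE 0.0861). That call was lost with an estimated correlation (adjusted p = 0.175 with an estimated correlation), without _x_at and _s_at probe sets (0.46), when only these 6 arrays were fitted (0.14), with array weights (0.105) and without dim probe sets (0.0916). It was also lost after quantile normalisation (0.0617) or cyclic loess (0.0605), and with the replicate number as a block (0.0586). The same held without knockdown replicate 2 (0.0565), overexpression replicate 2 (0.121) or overexpression replicate 3 (0.0719).

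The fibroblast marker list also moved with the arrays labelled knockdown: 2 of 13 rose, none fell and 11 were not called, also adjusted over the list alone (camera adjusted p = 0.0372, but adjusted p = 0.175 with an estimated correlation, 0.46 without _x_at and _s_at probe sets, 0.115 with the mean of all probe sets of a gene, 0.0717 after quantile normalisation, 0.0819 after cyclic loess, 0.0604 when only these 6 arrays were fitted, and 0.0515 to 0.0565 without control replicate 1, knockdown replicate 2 or overexpression replicate 2). The collagen gene COL1A1 rose by 1.46 (SE 0.0975), while COL3A1 was at 0.11 (SE 0.0642, adjusted p = 0.385). LUM rose by 1.60 (SE 0.163) on a probe set with the ending _s_at and was at 0.10 (adjusted p = 0.524) without such probe sets. Leukocyte markers had 2 of 14 higher and 12 not called, also adjusted over the list alone (CORO1A 1.06, SE 0.171; LCP1 0.66, SE 0.133; camera adjusted p = 0.398). No endothelial marker of 12 and no packaging cell marker of 12 was called over all genes or over the list alone (camera adjusted p = 0.746 and 0.875).

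The remaining 11 lists were not called in the arrays labelled knockdown. Airway secretory and mucin genes had 4 of 20 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.966). The secreted proteins LCN2 (-1.50, SE 0.175) and SLPI (-1.18, SE 0.112) were lower. Squamous and basal genes had 3 of 16 higher and 1 lower, also adjusted over the list alone (0.108). The cornified envelope gene IVL was at 1.22 (SE 0.172) and SERPINB5 at -1.11 (SE 0.178). Epithelial junction and polarity had 2 of 23 higher and 4 lower (5 and 5 adjusted over the list alone; 0.966). The tight junction gene CGN was at 0.70 (SE 0.0698) and CLDN1 at -1.30 (SE 0.143). Fatty acid and lipid synthesis had 4 of 23 higher and 1 lower (6 and 1 adjusted over the list alone; 0.101). The desaturase SCD was at 0.75 (SE 0.103) and the lipid droplet protein PLIN2 at -0.96 (SE 0.0726). ERK pathway response had 3 of 27 higher and 4 lower, also adjusted over the list alone (0.398). TGF-beta response had 3 of 20 higher and 3 lower (4 and 4 adjusted over the list alone; 0.966). NF-kB and inflammatory mediators had 1 of 25 higher and 1 lower, also adjusted over the list alone (0.62; the chemokine CXCL8 -0.72, SE 0.131). Wnt and intestinal-type genes had 3 of 19 higher, also adjusted over the list alone (0.398), led by DKK1. Apoptosis regulators had 2 of 21 higher and 4 lower, also adjusted over the list alone (0.167; BCL2A1 1.57, SE 0.228). NRF2 and xenobiotic response had 4 of 27 higher and 3 lower, also adjusted over the list alone (0.376). Of the KLF5 targets reported in other cells, 6 of 26 rose and 3 fell (7 and 4 adjusted over the list alone; 0.0695). The prostaglandin synthase PTGES was at 0.95 (SE 0.0889) and the growth factor carrier FGFBP1 at 1.08 (SE 0.134). Median, mean and test direction did not share a sign for the airway secretory, junction, TGF-beta and packaging cell lists.

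In all, 6208 of 54613 probe sets were called (11136 when only these 6 arrays were fitted), 3113 higher and 3095 lower, 426 of them with an absolute log2 fold change of at least 1. By gene, 1649 were higher and 1369 lower. The 3 arrays of one group all lay above those of the other for 40.9% of the 19775 genes, against 10% by chance. Leaving out 1 array gave 3671, 3898 and 4005 probe sets (knockdown replicates 1, 2 and 3), 4029 and 3799 (control replicates 1 and 2) and 12049 (overexpression replicate 2). All 6208 were among the last, with the same sign. That overexpression array enters this comparison only through the estimate of spread.

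Arrays labelled overexpression against control asked which genes differ after KLF5 was added, though KLF5 signal was not above control in them. The cornified envelope precursor SPRR1B (2.93, SE 0.169, adjusted p = 2.7e-05), surfactant protein B, SFTPB (2.91, SE 0.138, adjusted p = 1.65e-05), and AQP4 (2.88, SE 0.176) rose most. They were followed by the glycosyltransferase B3GNT6 (2.64, SE 0.185), the desmosome protein DSP (2.35, SE 0.206), the adhesion molecule CEACAM6 (2.16, SE 0.157) and the secreted protein ISM1 (2.09, SE 0.145). The largest falls were in INHBE (-2.35, SE 0.161), TCIM (-2.17, SE 0.127), the death-associated kinase DAPK1 (-2.01, SE 0.0757, adjusted p = 6.57e-06) and TCN1 (-1.80, SE 0.158). HSD17B6, a steroid dehydrogenase, also rose (1.82, SE 0.0827), and NHSL1 (-1.57, SE 0.222) and the histone deacetylase HDAC9 (-1.48, SE 0.139) fell. Overexpression replicate 2 added to the fall of NHSL1, which read 8.29, 7.34 and 8.35 in replicates 1 to 3. Without that array all 411 named gene results, over the 3 comparisons, kept their direction and call. Some calls rested on a single probe set. Without _x_at and _s_at probe sets, VGLL1 went from -1.66 (SE 0.0903) to 0.03 (adjusted p = 0.831), CMAHP from 1.88 to 0.32 (adjusted p = 0.281) and ADGRE2 from 1.85 to 0.28 (adjusted p = 0.155). The call of CDK5R1 (-1.52, SE 0.273) was lost with fewer arrays at similar folds: -1.55 without control replicate 1 (adjusted p = 0.0509) and -1.40 without control replicate 2 (adjusted p = 0.0637).

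Squamous and basal genes rose in the arrays labelled overexpression: of 16 measured, 10 rose, none fell and 6 were not called, also adjusted over the list alone (camera adjusted p = 1.2e-08, but adjusted p = 0.109 with an estimated correlation). Besides SPRR1B they included the calcium-binding protein S100A2 (1.45, SE 0.133) and the serpin SERPINB5 (1.55, SE 0.178). Of 16 alveolar type II and surfactant members, 7 rose, 1 fell and 8 were not called (8 and 1 adjusted over the list alone; camera adjusted p = 0.00304, but adjusted p = 0.112 with an estimated correlation and 0.0618 without _x_at and _s_at probe sets). The phosphate transporter SLC34A2 was at 1.66 (SE 0.229) and NAPSA at 0.55 (SE 0.0697) beside SFTPB. Integrin and matrix adhesion had 10 of 27 higher, 2 lower and 15 not called (12 and 2 adjusted over the list alone; camera adjusted p = 0.00187, but adjusted p = 0.112 with an estimated correlation and 0.162 without _x_at and _s_at probe sets), including the integrin chains ITGA2 (1.34, SE 0.146) and ITGA3 (0.98, SE 0.148). In the ion channel and transporter list, 4 of 19 rose, none fell and 15 were not called (5 adjusted over the list alone; camera adjusted p = 0.0344). The potassium channel KCNN4 was at 1.44 (SE 0.122). The channel list's call was lost with an estimated correlation (adjusted p = 0.262 with an estimated correlation), without control replicate 3 (0.0787), overexpression replicate 1 (0.134) or overexpression replicate 3 (0.105), and without dim probe sets (0.0543).

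Mitosis genes fell: of 30 measured, 18 fell, none rose and 12 were not called (25 lower adjusted over the list alone; camera adjusted p = 3.45e-17, but adjusted p = 0.109 with an estimated correlation). The spindle protein DLGAP5 fell by 0.63 (SE 0.0723), the cyclin CCNB2 by 0.76 (SE 0.0881) and the kinetochore protein NDC80 by 0.71 (SE 0.0837). CDC25C was also lower (-0.79, SE 0.0843) on a probe set with the ending _s_at, and without such probe sets it read 0.02 (adjusted p = 0.887). DNA replication had 2 of 29 higher, none lower and 27 not called, also adjusted over the list alone (camera adjusted p = 0.0185). LIG1 was at 0.61 (SE 0.0986). The replication call was lost with an estimated correlation (adjusted p = 0.539 with an estimated correlation), without control replicate 2 (0.102), without overexpression replicate 3 (0.299) and with fry (0.101).

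Interferon response had 13 of 30 lower, 2 higher and 15 not called (17 and 3 adjusted over the list alone; camera adjusted p = 1.2e-08, but adjusted p = 0.112 with an estimated correlation). IFIT3 fell by 1.74 (SE 0.0768), IFIT2 by 1.43 (SE 0.0809) and IFIT1 by 1.62 (SE 0.125). Unfolded protein and amino acid stress had 8 of 26 lower, none higher and 18 not called (10 lower adjusted over the list alone; camera adjusted p = 5.3e-06, and adjusted p = 0.04 with an estimated correlation). CHAC1 was at -0.77 (SE 0.0947). Unfolded protein stress was the only list whose call held with an estimated correlation in this comparison. Among apoptosis regulators 2 of 21 fell, none rose and 19 were not called (4 lower adjusted over the list alone; camera adjusted p = 0.0126). The BH3-only gene BCL2L11 was at -0.40 (SE 0.0688). The apoptosis call was lost with an estimated correlation (adjusted p = 0.167 with an estimated correlation), with array weights (0.0611), without dim probe sets (0.0889) and with the mean of all probe sets of a gene (0.0554).

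Leukocyte markers moved with the arrays labelled overexpression: 2 of 14 rose, none fell and 12 were not called (4 higher adjusted over the list alone; camera adjusted p = 0.0107, but adjusted p = 0.318 with an estimated correlation). LCP1 (0.63, SE 0.133) and CORO1A (0.80, SE 0.171) were those called. Both calls were lost without control replicate 1 (0.67 and 0.84, adjusted p = 0.0721 and 0.0774) or control replicate 2 (0.52 and 0.73, adjusted p = 0.104 and 0.112), and that of CORO1A without control replicate 3 (0.82, adjusted p = 0.0629). Of 13 fibroblast markers 1 rose (2 adjusted over the list alone; camera adjusted p = 0.106), LUM at 1.02 (SE 0.163) on a probe set with the ending _s_at and at 0.04 (adjusted p = 0.744) without such probe sets. Packaging cell markers had 1 of 12 higher, also adjusted over the list alone (0.567), and endothelial markers none of 12 by either count (0.624).

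Further lists were not called in the arrays labelled overexpression. Airway secretory genes had 2 of 20 higher and 1 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.567). The mucins MUC4 (0.76, SE 0.0722) and MUC16 (0.77, SE 0.123) were higher. Junction and polarity genes had 2 of 23 higher and 2 lower (6 and 5 adjusted over the list alone; 0.851), with DSP above and CLDN1 (1.34, SE 0.143) higher. Mesenchymal transition had 2 of 20 higher, also adjusted over the list alone (0.167; S100A4 1.27, SE 0.0995). Among p53 targets 3 of 20 rose and 3 fell (4 and 3 adjusted over the list alone; 0.624). Cholesterol genes had 2 of 18 higher (3 adjusted over the list alone; 0.0892), and fatty acid and lipid genes 2 of 23 higher and 2 lower, also adjusted over the list alone (0.712). Hypoxia and glycolysis had 3 of 27 higher and 1 lower (7 and 4 adjusted over the list alone; 0.907). ERK pathway response had 8 of 27 higher and 1 lower (9 and 2 adjusted over the list alone; 0.0983; SPRY4 0.50, SE 0.0715). TGF-beta response had 4 of 20 lower, also adjusted over the list alone (0.167; ID3 -0.80, SE 0.0997). NF-kB and inflammatory mediators had 1 of 25 higher and 3 lower (1 and 4 adjusted over the list alone; 0.268). The adhesion molecule ICAM1 was at 1.31 (SE 0.0918) and CXCL8 at -1.02 (SE 0.131). Wnt and intestinal-type genes had 1 of 19 higher, also adjusted over the list alone (0.727), and the KLF family 1 of 19 higher and 2 lower, also adjusted over the list alone (0.567; KLF11 -0.59, SE 0.0963). The KLF5 targets reported in other cells had 3 of 26 higher and 4 lower (6 and 7 adjusted over the list alone; 0.852), and NRF2 and xenobiotic response 2 of 27 higher and 3 lower, also adjusted over the list alone (0.537; CYP1B1 -1.28, SE 0.119). Median and mean or test direction differed in sign for the fatty acid, KLF5 target and NRF2 lists.

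Against control, 3340 probe sets were called in the arrays labelled overexpression (1097 when only these 6 arrays were fitted), 1354 higher and 1986 lower. The excess of lower calls was smaller after quantile normalisation (1555 higher and 1764 lower), absent without control replicate 1 (631 and 637), and not seen among the 205 with an absolute log2 fold change of at least 1 (107 and 98). By gene, 683 were higher and 962 lower, and the groups did not overlap for 29.2% of genes, against 10% by chance. Leaving out 1 array gave 6165 (overexpression replicate 2), 1268, 1303 and 2225 (control replicates 1, 2 and 3) and 2150 and 2225 (knockdown replicates 1 and 3). Of the 3340, 3308 were called with the same sign without overexpression replicate 2.

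**Figure D3:**
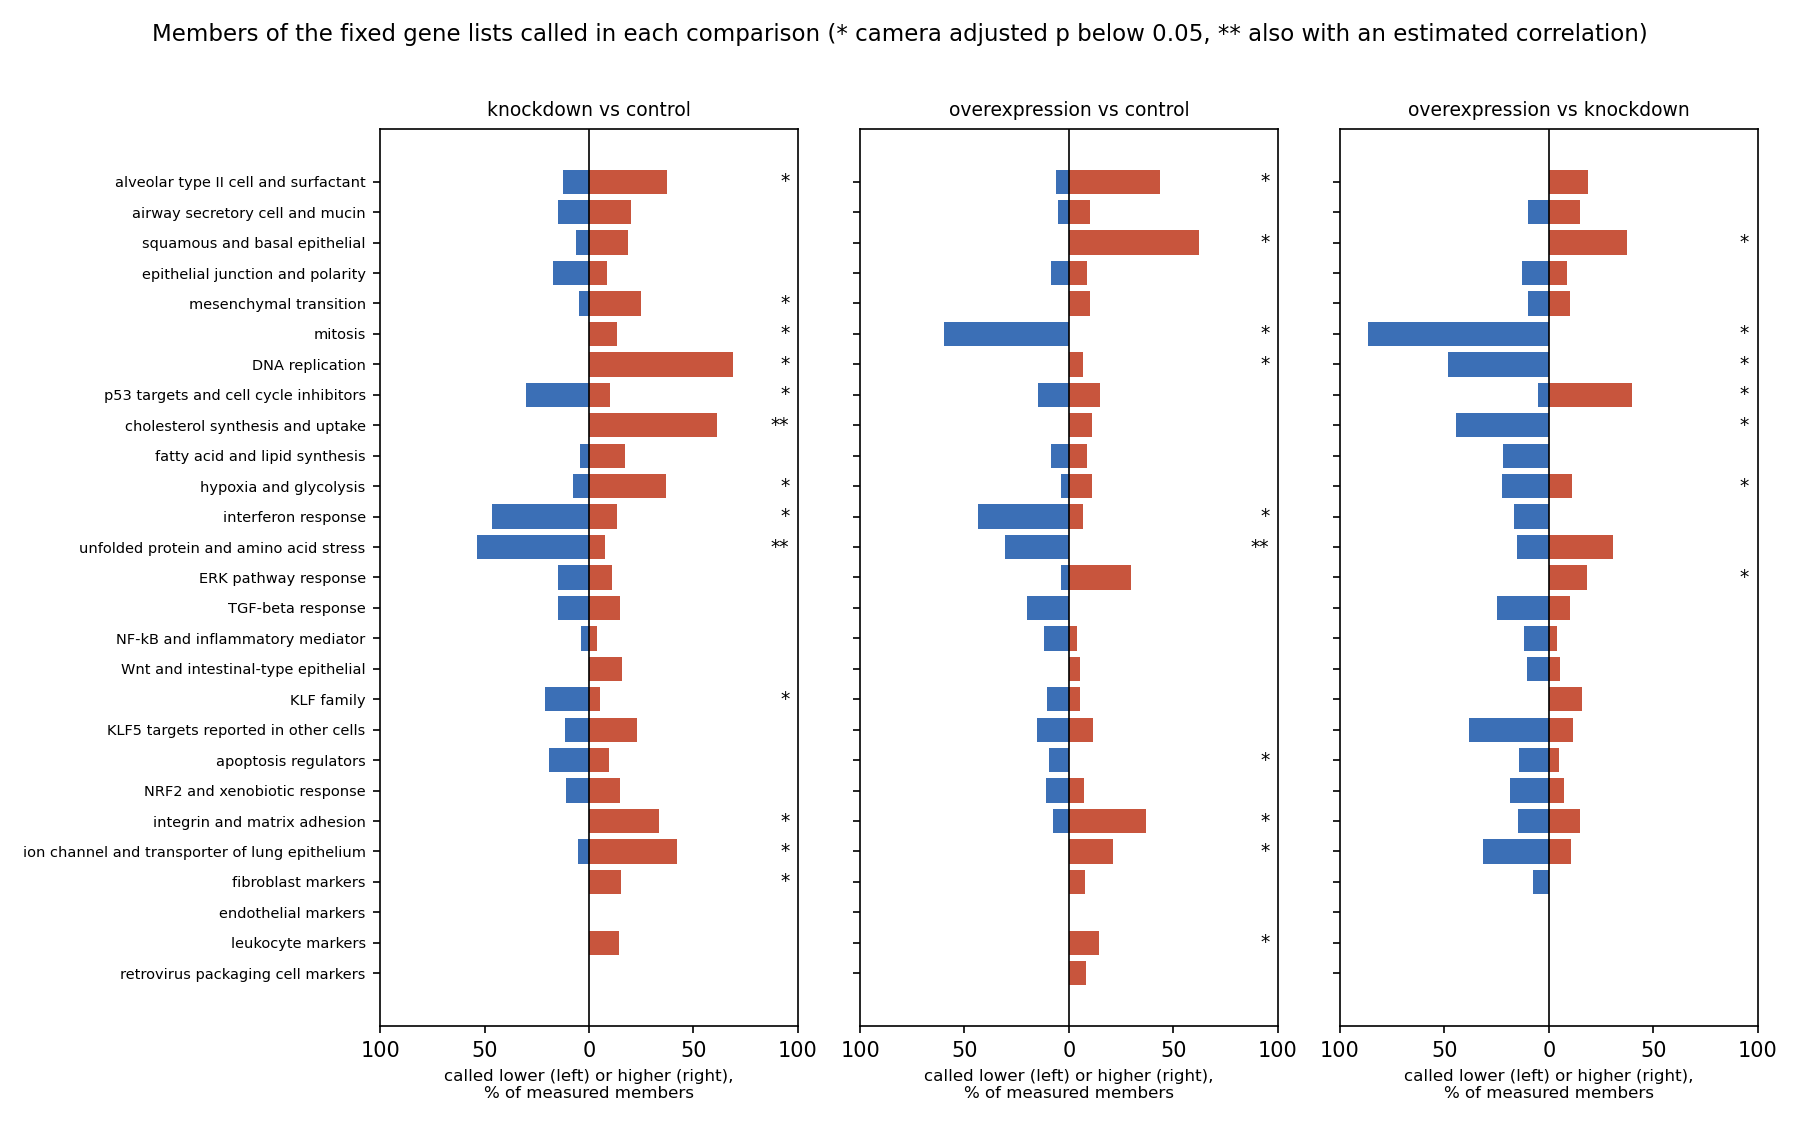
Percent of measured members of each fixed gene list called higher (right) or lower (left) in each comparison, with 1 star where camera's adjusted p was below 0.05 and 2 stars where it also was with an estimated correlation. The largest shares were DNA replication (20 of 29) and cholesterol synthesis (11 of 18) higher in the arrays labelled knockdown, squamous genes (10 of 16) higher and mitosis (18 of 30) lower in those labelled overexpression, and mitosis (26 of 30) lower in overexpression against knockdown, and of these only cholesterol synthesis has 2 stars.

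Arrays labelled overexpression were also set against those labelled knockdown, a comparison in which control arrays enter the estimate of spread but not the fold changes. Mitosis genes differed most: 26 of 30 were lower in the arrays labelled overexpression, none higher and 4 not called (29 lower adjusted over the list alone; camera adjusted p = 2.28e-23, but adjusted p = 0.0817 with an estimated correlation). KIF20A was at -1.26 (SE 0.0929) and DLGAP5 at -1.04 (SE 0.0723). Lower too were 14 of 29 DNA replication genes, with none higher and 15 not called (20 lower adjusted over the list alone; camera adjusted p = 2.88e-11, but adjusted p = 0.279 with an estimated correlation; POLE2 -0.75, SE 0.0836). Of cholesterol genes, 8 of 18 were lower, with none higher and 10 not called (10 lower adjusted over the list alone; camera adjusted p = 4.12e-08, but adjusted p = 0.055 with an estimated correlation; INSIG1 -1.81, SE 0.0991). Hypoxia and glycolysis had 6 of 27 lower, 3 higher and 18 not called (16 and 3 adjusted over the list alone; camera adjusted p = 0.00113, but adjusted p = 0.375 with an estimated correlation; ENO2 -1.19, SE 0.127). Squamous and basal genes were higher, 6 of 16, with none lower and 10 not called (8 and 1 adjusted over the list alone; camera adjusted p = 0.000177, but adjusted p = 0.294 with an estimated correlation), SPRR1B by 2.88 (SE 0.169) and SERPINB5 by 2.67 (SE 0.178). So were p53 targets and cell cycle inhibitors, 8 of 20, with 1 lower and 11 not called (10 and 2 adjusted over the list alone; camera adjusted p = 0.00144, but adjusted p = 0.294 with an estimated correlation), including the growth arrest gene GADD45A (0.54, SE 0.0722). ERK pathway response had 5 of 27 higher, none lower and 22 not called (8 higher adjusted over the list alone; camera adjusted p = 0.00661, but adjusted p = 0.346 with an estimated correlation and 0.0794 without overexpression replicate 3). The growth factor HBEGF was at 1.12 (SE 0.166). No list call held with an estimated correlation here.

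Single genes that separated the labelled groups most included ARG2 (3.69, SE 0.144, adjusted p = 4.46e-06), DSP (2.76, SE 0.206) and SFTPB (2.55, SE 0.138), higher in the arrays labelled overexpression. DKK1 (-2.99, SE 0.218), AQP3 (-2.58, SE 0.169), ABCG2 (-2.01, SE 0.172) and DAPK1 (-1.88, SE 0.0757) were lower in them. AQP4 did not differ beyond the spread between replicates (-0.11, SE 0.176, adjusted p = 0.758). For the other 20 lists camera's adjusted p ran from 0.0507, for the KLF5 targets reported in other cells (3 higher and 10 lower of 26; 4 and 11 adjusted over the list alone), to 0.83, for endothelial markers. Signs of median, mean and test differed for the junction, endothelial, Wnt and fibroblast lists. In total 4001 probe sets were called (2081 when only these 6 arrays were fitted), 1519 higher and 2482 lower, and 336 by at least 1. The groups did not overlap for 30.4% of genes, against 10% by chance. Leaving out knockdown replicates 1, 2 or 3 gave 1915, 2012 and 2197 calls, and leaving out overexpression replicate 2 gave 6607, which held 3955 of the 4001 with the same sign.

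A factor lowered in one group and raised in the other would move its targets in opposite directions against control. Among genes called in both comparisons, 63 went opposite ways: 19 lower in the arrays labelled knockdown and higher in those labelled overexpression, and 44 the reverse. The cytokine TNFSF15 (-1.48 and 1.31, SE 0.139), the tight junction protein CLDN1 (-1.30 and 1.34, SE 0.143) and the serpin SERPINB5 (-1.11 and 1.55, SE 0.178) fell in the first and rose in the second. The alcohol dehydrogenase ADH1C (1.25 and -0.86, SE 0.102), the interleukin receptor IL7R (1.06 and -0.77, SE 0.143) and the antiviral membrane protein IFITM1 (0.80 and -0.71, SE 0.0922) did the reverse. BBOX1, a carnitine synthesis enzyme, read -0.71 and 1.53 (SE 0.19), and TMEM150C 0.79 and -0.88 (SE 0.206). The call of IL7R in the arrays labelled overexpression was lost without control replicate 1 (adjusted p = 0.0619) or control replicate 2 (adjusted p = 0.0611), at a fold of -0.77 in each. That of BBOX1 in the arrays labelled knockdown was lost without any 1 of the knockdown or control arrays (adjusted p from 0.0593, without control replicate 3, to 0.155, without control replicate 2, at folds of -0.80 and -0.63), as was that of TMEM150C (adjusted p from 0.0646, without control replicate 2, to 0.126, without control replicate 3, at folds of 0.88 and 0.62). TMEM150C was also lost in the arrays labelled overexpression without knockdown replicates 1, 2 or 3 (adjusted p = 0.0609, 0.0619 and 0.0631) or control replicates 1 or 2 (adjusted p = 0.146 and 0.149, at folds of -0.80 and -0.78).

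**Figure D4:**
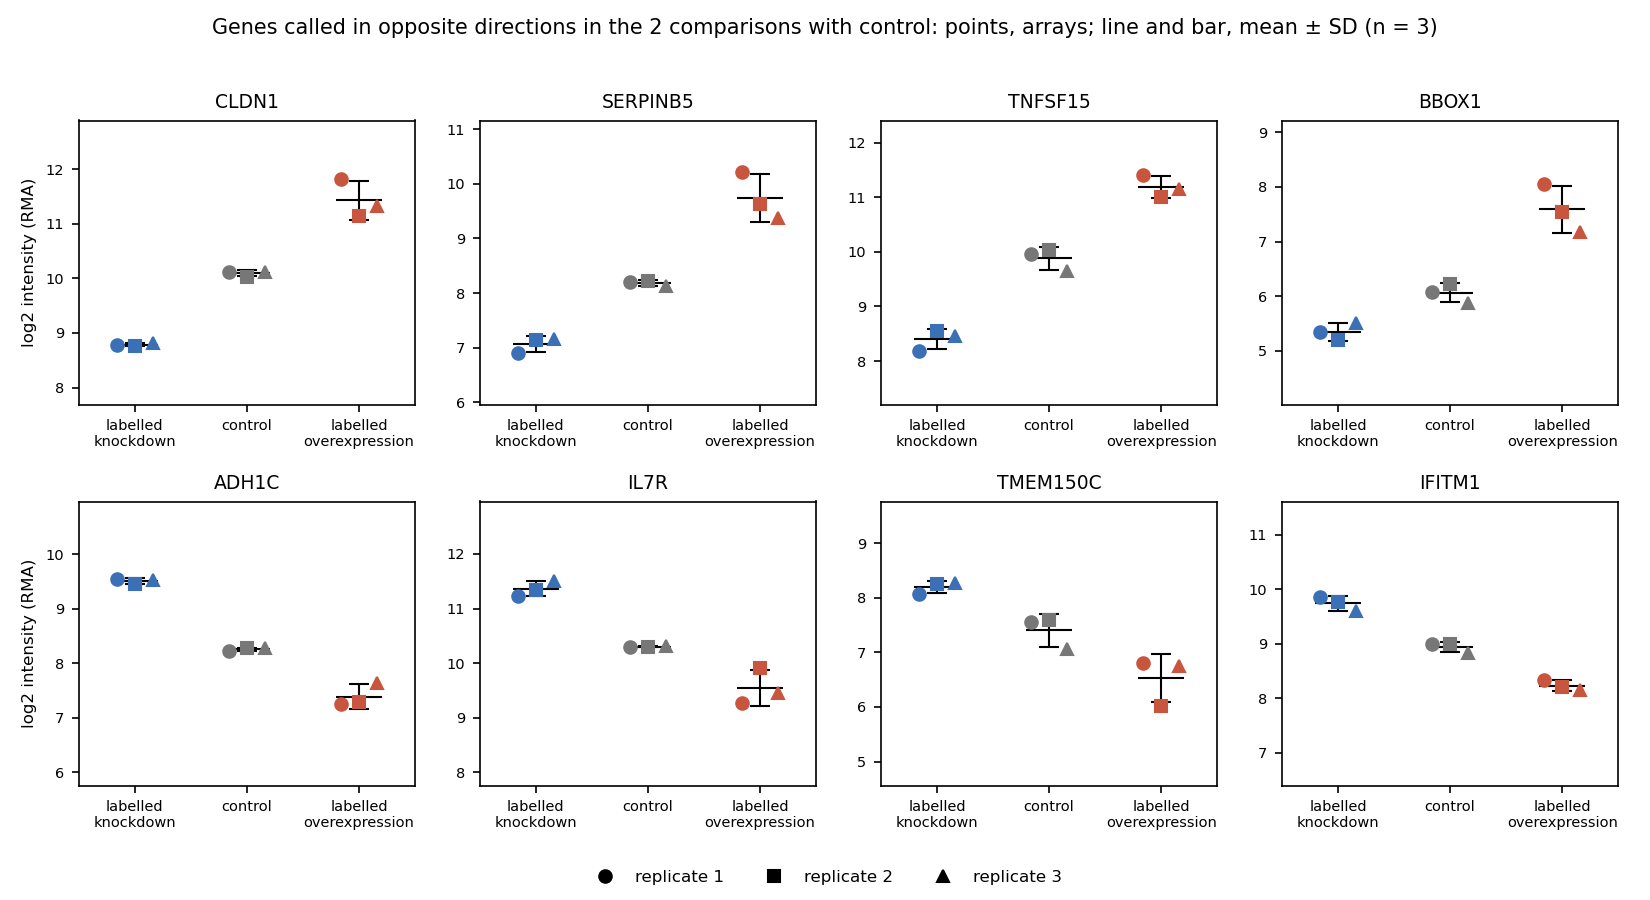
Log2 intensity in each array of 8 genes called in opposite directions against control in the 2 labelled groups, with mean and SD of 3 arrays per group. TNFSF15, CLDN1, SERPINB5 and BBOX1 are lowest in the arrays labelled knockdown, and ADH1C, IL7R, TMEM150C and IFITM1 are highest in them; some calls of BBOX1, TMEM150C and IL7R were lost when 1 array was left out.

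By probe set, 98 were called in opposite directions, 26 lower then higher and 72 higher then lower, where independent lists of these sizes would share 76.7 and 113. Without 1 array the 98 became 264 (overexpression replicate 2), 50, 53 and 55 (knockdown replicates 1, 2 and 3) and 33, 30 and 48 (control replicates 1, 2 and 3). Far more, 1786, were called in the same direction: 733 higher in both and 1053 lower in both, where independent lists would share 77.2 and 113. By gene these were 405 and 494. Without overexpression replicate 2 the 1786 became 3843. The count was 987, 1073 and 1066 without knockdown replicates 1, 2 and 3, and 730, 688 and 1212 without control replicates 1, 2 and 3. AQP4, B3GNT6, HSD17B6, TMT1B and S100A4 rose in both labelled groups, and INHBE, TCIM, TCN1, IFIT1 and IFIT3 fell in both. Both comparisons use the same 3 control arrays, which cannot be split into parts of at least 2. Some of the excess in the same direction, and of the shortfall in opposite directions, may come from them. The correlation of the log2 fold changes across probe sets, which are not independent replicates, was 0.505, against 0.501 in 20 simulations of unchanged groups, and 68.4% of probe sets had the same sign, against 66.7%. The covariance was 0.0312, against 0.00785 simulated, a difference of 0.0233. No probe set was called in both comparisons in the simulations. The simulated groups had no changed probe set, so hardly any call was possible and this does not test the overlap.

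**Figure D5:**
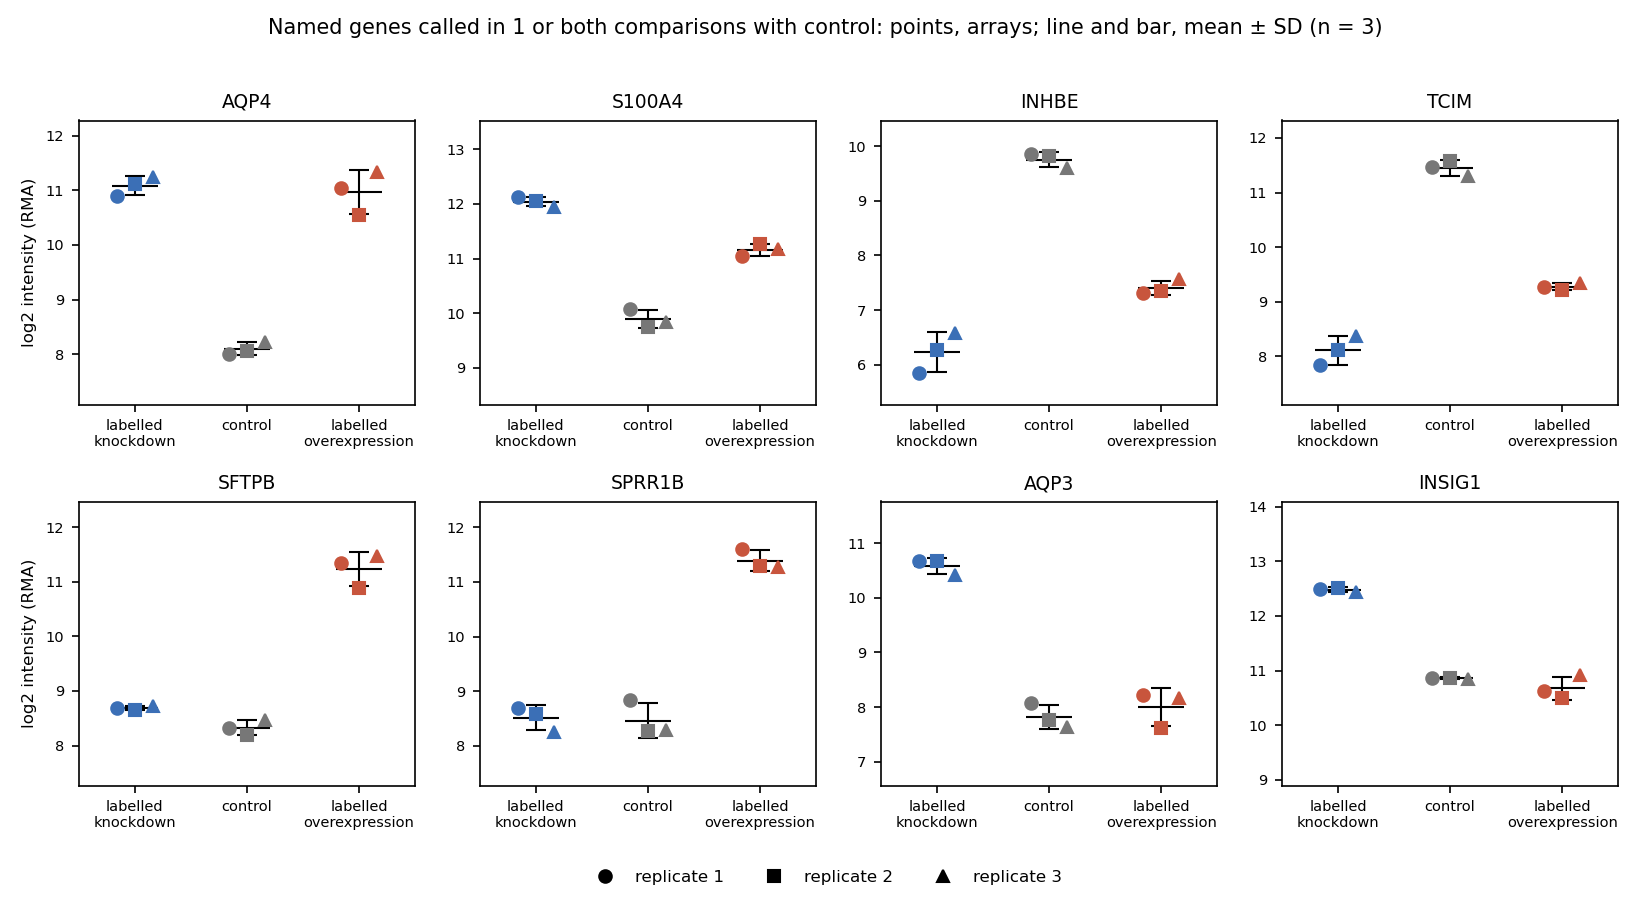
Log2 intensity in each array of 8 genes, with mean and SD of 3 arrays per group: AQP4, S100A4, INHBE and TCIM moved the same way against control in both labelled groups, SFTPB and SPRR1B rose in the arrays labelled overexpression, and AQP3 and INSIG1 in those labelled knockdown. AQP4 averaged 8.10 in control, 11.09 in the arrays labelled knockdown and 10.97 in those labelled overexpression.

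Over the 3 groups together, the F test called 7591 probe sets. The count was 4494, 4707 and 4785 without knockdown replicates 1, 2 and 3, 4789 and 4744 without control replicates 1 and 2, and 13333 without overexpression replicate 2.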

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

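The mean of both KLF5 probe sets was an alternative chosen after the data had been seen, and all others were planned. Of the 411 named gene results 264 kept their direction and side of the threshold in every alternative run, and of 7294 values 6642 did, 641 lost the call and 11 reversed. Of the 600 values of the 30 called lists 531 kept the call, 69 lost it and 0 reversed, and 3 lists kept it throughout (cholesterol in the arrays labelled knockdown, unfolded protein stress in both labelled groups). The counts of probe sets called (6208, 3340 and 4001 for knockdown and overexpression against control and overexpression against knockdown, 7591 by the F test, 98 in opposite directions) moved most. Array weights gave 12388, 9159, 10604, 16504 and 376. Without _x_at and _s_at probe sets, so with fewer tests, they were 3577, 1932, 2332, 4409 and 57. Fits with only the 2 groups compared, which change the residual spread, gave 11136, 1097 and 2081. A log2 fold change of at least 1 left 426, 205, 336, 716 and 6, an adjusted p below 0.01 left 3237, 1083, 1696, 3647 and 28, and a test per gene gave 3379, 2057, 2241 and 4194. The replicate number as a block gave 2199 for overexpression against control, though the numbers did not pair the arrays. Leaving out 1 array gave 3671 to 12049, 1268 to 6165, 1915 to 6607, 4494 to 13333 and 30 to 264, each highest without overexpression replicate 2, and 8 to 14, 8 to 12 and 7 to 10 lists called (13, 10 and 7 with all arrays). With an estimated correlation 2, 1 and 0 lists were called, and fry called 17 in overexpression against knockdown. KLF5 was at -0.487277 (knockdown) and -0.606425 (overexpression) as the mean of both probe sets, past the threshold (adjusted over genes) unlike the brighter one alone, and at -1.01887 (overexpression) on the dimmer probe set. Leaving out 1 array gave -0.512735 to -0.21248 and -0.44967 to -0.06543 for the brighter one. Reversals came without _x_at and _s_at probe sets, where another probe set stood for the gene: against control FN1 -0.0032, TMT1A -0.0320667 and VGLL1 -0.0121133 (knockdown) and CDC25C 0.0247233, SMAD6 0.0676367 and VGLL1 0.03247 (overexpression), and in overexpression against knockdown CDC25C 0.0706433, HOPX -0.06026, TGFB1 0.17949, TMT1A 0.174663 and VGLL1 0.0445833. None of these 11 values passed the threshold (adjusted p from 0.41 to 0.994), so none shows an opposite change. In knockdown against control the overexpression arrays enter only the estimate of spread. The rise there from 6208 to 12049 calls without overexpression replicate 2 therefore comes from that estimate. For other moves, unless said above, the cause was not tested. Signal over background limits the folds of dim probe sets, which RMA compresses.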

Other observations

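The splits were planned, and the tests of snoRNA hosts, glucocorticoid-induced genes, replicate 2, exchanged labels, shared controls and vector or batch were chosen after the data had been seen. Of 10 measured transcripts that host small nucleolar RNAs, 4 fell in the arrays labelled knockdown, 1 rose and 5 were not called. The list was drawn up because members had been seen to fall, so its test (camera in limma, p = 0.00623 unadjusted, and p = 0.123 with an estimated correlation) restates that and does not show a joint fall. EPB41L4A-AS1 fell by 1.29 (SE 0.0769), SNHG17 by 0.82 (SE 0.0711), SNHG32 by 0.51 (SE 0.078) and ZFAS1 by 0.51 (SE 0.0633), while DANCR rose by 0.60 (SE 0.121). In the arrays labelled overexpression 1 of the 10 fell (camera in limma, p = 0.203 unadjusted, and p = 0.436 with an estimated correlation).

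Surfactant genes of alveolar cells respond to glucocorticoids, so glucocorticoid-induced genes were tested in the arrays labelled overexpression, where SFTPB rose. Of 16 measured, 2 rose, 2 fell and 12 were not called (camera in limma, p = 0.698 unadjusted, and p = 0.752 with an estimated correlation), so no joint rise was called. SGK1 (0.41, SE 0.0859, adjusted p = 0.0209) and DUSP1 (0.30, SE 0.0669, adjusted p = 0.0291) rose. TSC22D3 (-0.76, SE 0.0617, adjusted p = 0.000204) and GADD45B (-0.54, SE 0.109, adjusted p = 0.0179) fell. Genes that moved alike in both labelled groups, named after their values were seen, included the neuropeptide NMU (1.70 in the arrays labelled knockdown and 1.64 in those labelled overexpression, SE 0.187), the LIM protein LMO3 (1.31 and 1.45, SE 0.0794), the mucin-type glycosyltransferase GALNT5 (1.37 and 1.28, SE 0.0913), the protein C receptor PROCR (1.52 and 1.26, SE 0.182) and the hexokinase HKDC1 (-1.49 and -1.38, SE 0.226).

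Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real split called 6208, 3340 and 4001 probe sets (knockdown against control, overexpression against control, overexpression against knockdown), and 1 of the 10 splits, the real one, gave as many; the highest other split called 0 in each. For lists the real counts were 13, 10 and 7, the highest others 9, 7 and 7, and 1, 1 and 3 of the 10 splits gave as many. For all 9 arrays, 1 of 100 drawn splits, the real one, gave 7591 probe sets by the F test (highest other 2230), so a random grouping of these arrays is argued against for that count. The replicates may be technical, so this does not tell an effect of KLF5 from any other difference between the cultures. For the 98 in opposite directions, 1 of 100 gave as many (highest other 0), but only 2 of the 99 other splits called any probe set in both comparisons, so these splits do not test that overlap. The 98 are fewer than independent lists would share (76.7 and 113 for the 2 directions). Both comparisons subtract the same control arrays, which favours the same sign, so this shortfall does not argue against opposite regulation.

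Overexpression replicate 2 stood apart from all other arrays. A stronger dose of the same response is argued against: its difference from replicate 1 correlated at 0.002124 with the difference of replicate 3 from control. A large share of RNA from leukocytes, endothelial cells, packaging cells or fibroblasts is argued against. The upper 95% limit of the median deviation stayed below the bound of 0.5 for leukocyte (median 0.248, 0.0289 to 0.361), endothelial (0.166, 0.00544 to 0.354), packaging cell (0.114, -0.037 to 0.206) and fibroblast markers (-0.0175, -0.102 to 0.0791). Other cell types, such as another epithelial line, had no such list, so their RNA was not tested. Leukocyte and endothelial markers did lie above 0 (11 of 14 and 10 of 12 higher; CORO1A, the brightest leukocyte member at 9.185 in the other arrays, read 9.89, but LYZ 5.48, against 5.70 and 5.82 in replicates 1 and 3, and KDR, the brightest endothelial one at 10.17, read 8.86), so a small share is not excluded. Array or RNA quality alone stays open: deviations of 2 probe sets of 1 gene correlated at 0.1154 (0.70 for knockdown minus control, 0.213 for replicate 1 minus replicate 3), the 3' minus 5' difference was lowest for ACTB (1.25, others 1.3 to 1.63) and within range for GAPDH (0.225, others 0.0908 to 0.317), and 18S signal was highest (14.41, others 12.02 to 14.24).

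KLF5 signal was not higher in the arrays labelled overexpression. An exchange of the knockdown and overexpression labels would leave KLF5 higher in the arrays labelled knockdown. The dimmer probe set differed by -0.4211 (overexpression minus knockdown, adjusted p = 0.33) and the brighter by 0.18 (adjusted p = 0.671), so an exchange and correct labels cannot be told apart from KLF5, because neither difference passed the threshold. Whether the probe sets report the introduced sequence was not analysed here. A lower KLF5 level in both labelled groups stays open as well.

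Most probe sets called in both comparisons against control moved the same way. Spread between the 3 shared control arrays alone is argued against. The covariance of the log2 fold changes (0.03115) was 6.778 times that given by the control variance (0.004596). It was 3.98 times that given by the variance within all 3 groups, the floor of the simulation. Among all 840 assignments of the arrays to groups, the real one included, 20 and 11 gave as large a ratio. The spread within groups may be technical, so an offset common to the 3 control arrays is not tested by this. The ratio shows that groups differ by more than the spread within them, not that control is the group apart. Of the probe sets called in both, 94.8% moved the same way, but subtracting the same control arrays favours the same sign. That share therefore points to no cause. Over all probe sets the correlation of the log2 fold changes was 0.505, against 0.501 simulated for unchanged groups. The share with the same sign was 68.4%, against 66.7%. A difference of the control cells from both labelled groups by vector or batch stays open, since vector or batch would coincide with group. A shared response to a lower KLF5 level, or to the handling of both labelled groups, cannot be told apart from it for the same reason.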
